A study of Mus musculus with 21 samples.

How the data were processed

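RNA was sequenced from primary neurons that had been isolated from the hypothalamus of mouse embryos on embryonic day 14. The mice carried Tbx3 alleles flanked by loxP sites, which Cre recombinase can cut out. The cultures received an adenovirus carrying Cre (Ad-Cre) or one carrying green fluorescent protein (Ad-GFP), which is the control. Per the labels' protocols, the libraries came from 3 independent isolations, were made with a TruSeq RNA kit and were sequenced as paired 100 bp reads. There were 10 libraries labelled Ad-Cre and 11 labelled Ad-GFP.

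The values used were whole-number counts per named feature, as deposited by the authors in a table of 29955 features and 21 libraries. Per the submitters' processing notes, the counts were made with HTSeq 0.6.0 and the genome build was mm9. The aligner, the gene annotation, the strand setting and any filter were not given in the sources used here. Reads of a gene and of an overlapping or antisense gene may therefore not be separated, and near-identical family members such as the histone genes are uncertain. Every entry of the table had a feature name, and 5238 features had no count in any library. All 21 columns were matched to a library by title. Feature names were matched to GENCODE M21 transcripts of another build, GRCm38, only for current symbols, transcript length and GC content. A length was found for 22219 features, and no coordinates were used.

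Total counts per library ran from 17154066 to 30141849. The precision of a value follows from these totals: 1 count is worth 0.0332 CPM in the deepest library and 0.0583 in the shallowest, before scaling. Genes were kept by the edgeR function filterByExpr on the 6 groups of virus and isolation, which left 17442 features holding 99.97% of all counts. Library sizes were scaled by TMM factors. The main comparison used the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3, robust fits) with isolation as a covariate and all 21 libraries, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A log2 fold change is the libraries labelled Ad-Cre over those labelled Ad-GFP, and its standard error (SE) was taken from the F statistic. Changes within each isolation and the virus by isolation interaction came from a second model with 1 mean for each of the 6 groups, fitted to all 21 libraries so that the spread was shared. The Ad-GFP libraries alone were compared between isolations in a separate fit. Levels are in CPM, the usual counts relative to library size, with TMM-scaled sizes.

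For Tbx3, the mean log2 CPM difference, weighted over isolations, was also set against every arrangement of the virus labels within isolations (55440 arrangements, exact permutation test, two-sided, 0.1 CPM added before the log). The gene lists, 33 in all with 617 distinct genes, were fixed before the data were examined, as were the comparisons, the gene-naming rule and all alternatives not named otherwise. Of those genes, 614 were in the table. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on voom values with an inter-gene correlation of 0.01. The same list test with an estimated correlation, the fry test and an exact permutation of the mean list score per library were alternatives, of which the last was chosen after seeing the data. A list score is the mean log2 CPM (prior count 2) of the members, each centred on its mean over the libraries.

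The genes named are Tbx3; the 10 largest rises and 10 largest falls among genes past the threshold with a mean of at least 1 CPM and the same sign of the fitted difference in all 3 isolations, passing over predicted, Riken and identifier-only names; every tested member of the list of arcuate neuropeptides; up to 3 members with the smallest p of any other list; and the 5 genes with the smallest adjusted p for the interaction. The genes named for the differences between isolations in the Ad-GFP libraries, and the histone genes as a set, lie outside this rule and were chosen after values had been seen. Some genes that the rule selects are not reported here.

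One library has conflicting labels. The library titled Ad-Cre isolation 3 replicate 1 carries isolation 2 in its characteristics. The title was used, and the characteristic was an alternative. Over all tested genes this library lay nearest to Ad-Cre isolation 3 replicate 2. On the first principal component it lay at -44.03, against -44.07 and -38.63 in the other Ad-Cre libraries titled isolation 3. The Ad-Cre libraries of isolation 2 lay at 33.33 to 50.84. These values argue for the title, so the fits that use the characteristic probably misplace this library. The labels do not say whether libraries of one isolation came from separate cultures, so p-values measure the spread between these libraries, part of which may be technical. No pair of libraries within a group was a duplicate: the chi-square per degree of freedom was between 2.25 and 25.9 over 33 pairs.

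The alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no filter, a mean of at least 1 CPM, no isolation covariate, a block on the replicate number, isolation from the characteristics, counts summed per group, isolation as a random effect, thinning to the smallest library, leaving out each isolation or each library, and a 1.5-fold limit. Added after seeing the data were a correction for transcript length, a covariate for the non-neuronal score (the mean of the astrocyte, oligodendrocyte lineage and progenitor list scores), upper-quartile scaling of the list tests and a fit without both doubted libraries (the one with conflicting labels and Ad-GFP isolation 2 replicate 4). The scripts were tested on simulated data with 17442 genes. For the main comparison, 100% of 100 genes changed by 1 on the log2 scale and 98% of 100 genes changed by 0.5 were recovered, with 10 false calls. For the interaction, 89.5% of 200 genes changed by 1 in isolation 2 alone were recovered. With no gene changed, no gene was called. The simulated genes were drawn independently of each other, so these false calls do not cover shifts shared by many genes in a library. Other splits of the libraries were also made for the interaction with the virus effect shared by the isolations held in the offset, a step tested on simulated data and chosen after seeing the data.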

Results

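The data set holds gene counts of 21 libraries from hypothalamic neurons in primary culture, in which Tbx3 could be deleted by Cre. Tbx3 encodes a T-box transcription factor of the melanocortin neurons of the arcuate nucleus, and the series asks what its loss does in hypothalamic neurons. Isolation 1 gave 2 libraries labelled Ad-Cre and 2 labelled Ad-GFP, isolation 2 gave 5 and 6, and isolation 3 gave 3 and 3. Total counts per library ran from 17154066 to 30141849. Each library lay nearest, over all tested genes, to a library of its own isolation and its own virus (21 of 21). The first principal component held 41.4% of the variance and the second 31.9%, and both separated the isolations.

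Tbx3 was higher in the libraries labelled Ad-Cre than in those labelled Ad-GFP. Its log2 fold change was 1.01 ± 0.11 (SE, 10 against 11 libraries), a 2.01-fold difference (edgeR adjusted p = 1.82e-07). In isolation 1, Tbx3 was at 11.2 ± 0.562 CPM (SD, n = 2) in the libraries labelled Ad-Cre and at 4.53 ± 1.13 CPM (n = 2) in those labelled Ad-GFP. In isolation 2 the means were 1.51 ± 0.215 CPM (n = 5) and 1.05 ± 0.306 CPM (n = 6). In isolation 3 they were 16.3 ± 0.32 CPM (n = 3) and 7.45 ± 0.969 CPM (n = 3). The raw counts of Tbx3 were 276 and 306 against 102 and 131 in isolation 1, 39 to 52 against 17 to 38 in isolation 2, and 336 to 403 against 143 to 153 in isolation 3. In isolation 2 the CPM values overlapped, with a lowest value of 1.33 in the libraries labelled Ad-Cre and a highest of 1.36 in those labelled Ad-GFP. Of all 55440 arrangements of the virus labels within isolations, 10 gave a mean difference as large (exact permutation p = 0.00018, two-sided). With isolation taken from the characteristics instead of the title of 1 library, the log2 fold change was 1.52 ± 0.41 (edgeR adjusted p = 0.0268). The counts cover the whole gene, so reads from exons outside the loxP sites are included and a deletion need not lower them. Because the targeted gene went against the direction that a deletion would give, the arms are named by their labels throughout, and every direction below depends on those labels.

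**Figure D1:**
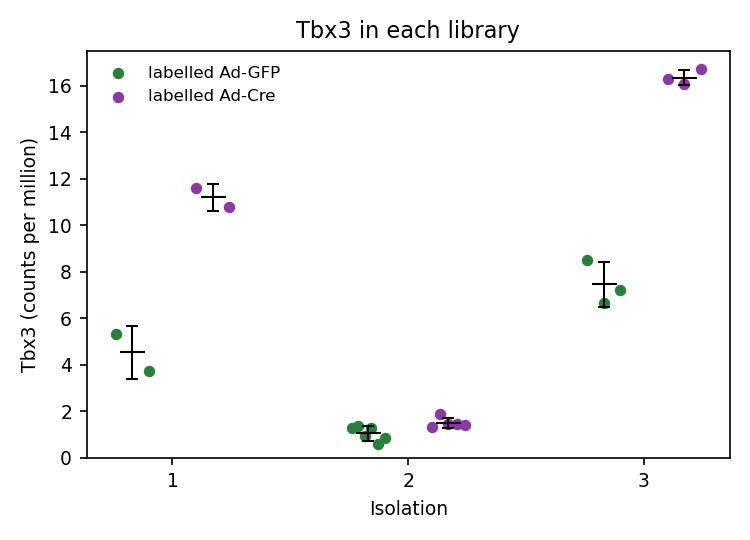
Tbx3 in CPM (vertical axis, from 0) for each library, by isolation (horizontal axis); points are libraries, bars are the mean and SD. The libraries labelled Ad-Cre lie at 10.8 CPM or more in isolation 1 and at 16.1 CPM or more in isolation 3, above all those labelled Ad-GFP there, while both arms lie below 2 CPM in isolation 2.

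Among genes past the threshold with the same sign in all 3 isolations and a mean of at least 1 CPM, the 10 largest rises in the libraries labelled Ad-Cre were led by genes of the oligodendrocyte lineage. Gpr17, a receptor of differentiating oligodendrocyte precursors, was 5.33-fold higher (log2 fold change 2.42 ± 0.23 SE). Mag and Bcas1, of maturing oligodendrocytes, were higher by 1.94 ± 0.30 and 1.93 ± 0.17 on the log2 scale, and Sox10, a transcription factor of that lineage, by 1.48 ± 0.11. Zfp488 and Gjc3, which oligodendrocytes also express, were higher by 1.34 ± 0.12 and 1.32 ± 0.13. Gfap, the intermediate filament of astrocytes, was higher by 1.45 ± 0.20, and Osmr, the oncostatin M receptor, by 1.32 ± 0.28. Within isolations, Mag, Gfap and Osmr passed in isolation 2 alone, and Mag was at 0.26 ± 0.97 in isolation 3. Plscr4 rose by 1.27 ± 0.13, and Mir715 by 1.27 ± 0.39. The call of Mir715 was lost with limma-voom (adjusted p = 0.074), without isolation 2 (0.175) or isolation 3 (0.082), and without Ad-Cre isolation 2 replicate 4 (0.0509) or Ad-Cre isolation 3 replicate 1 (0.0506). The largest falls among genes chosen in the same way were in Atp2a3, a calcium pump of the endoplasmic reticulum, at -1.40 ± 0.12, Pm20d1, which makes N-acyl amino acids, at -1.37 ± 0.16, and Il28ra at -0.97 ± 0.14. Slamf9 was at -0.77 ± 0.16 and did not pass without isolation 2. Its sign in isolation 1 rested on -9e-04 ± 0.76, and within isolations Il28ra and Slamf9 passed in isolation 2 alone. The other 6 were histone genes of the Hist1 cluster, from Hist1h1d at -1.36 ± 0.16 to Hist1h4i at -0.73 ± 0.09, with Hist1h1e at -1.09 ± 0.14, Hist1h2ac at -0.94 ± 0.11, Hist1h1c at -0.76 ± 0.09 and Hist1h2bg at -0.74 ± 0.11. These near-identical genes may share reads.

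Over all genes, 2473 were higher and 2068 lower in the libraries labelled Ad-Cre (edgeR quasi-likelihood test with isolation as covariate, 17442 genes tested). With upper-quartile scaling 2217 were higher and 2537 lower, so which direction held more genes depended on the scaling. Most changes were small: the median absolute log2 fold change of the 4541 genes was 0.199, and 590 of them (445 higher, 145 lower) differed by at least 1.5-fold. Of the 4541 genes, 3632 (80%) had the same sign in all 3 isolations, against 41.3% of all tested genes. With isolation taken from the characteristics instead of the title of 1 library, 1646 genes passed. With counts summed per virus and isolation 593 were higher and 137 lower (730 in all, 81.2% higher against 54.5%). Without isolation 2, which holds 11 of the libraries, 1239 passed, and with no isolation covariate 49 did. With a score of astrocyte, oligodendrocyte lineage and progenitor genes as a further covariate, chosen after seeing the data, edgeR called 0 genes (1229 at an unadjusted p below 0.05). That score followed the virus labels within isolations (r = 0.95 over 21 libraries), so the changes in all other genes and the rise of these marker genes were not separable in this fit.

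Genes that mark glia, neural progenitors and dividing cells rose in the libraries labelled Ad-Cre. Of 15 astrocyte markers 13 rose and none fell (median log2 fold change 0.86), among them Slc4a4 at 0.73 ± 0.07, Mlc1 at 0.91 ± 0.08 and the glycolytic enzyme Aldoc at 1.04 ± 0.09. Of 14 oligodendrocyte lineage markers 13 rose (median 0.96), including Pdgfra, the receptor that marks precursors, at 1.22 ± 0.14. Of 18 neural progenitor genes 16 rose (median 0.57), including Prom1 at 0.65 ± 0.06 and the intermediate filament Nes at 0.50 ± 0.05. Of 30 cell cycle genes 27 rose (median 0.76), including the centromere genes Cenpe at 0.77 ± 0.08 and Cenpf at 1.02 ± 0.10 and the spindle motor Kif11 at 0.71 ± 0.09. The median was 0.503, 1.01 and 0.753 in isolations 1, 2 and 3 for the astrocyte list, 1.11, 0.935 and 0.289 for the oligodendrocyte lineage list, 0.277, 0.586 and 0.489 for the progenitor list and 0.215, 0.861 and 0.805 for the cell cycle list. No cell cycle gene passed in isolation 1, and 7 of the 14 oligodendrocyte lineage genes had a virus by isolation interaction. The numbers that rose adjusted over the list alone were 14 astrocyte, 13 oligodendrocyte lineage, 17 progenitor and 28 cell cycle members. The camera adjusted p was 3.11e-18 for the astrocyte list, 1.39e-12 for the oligodendrocyte lineage list, 1.09e-16 for the progenitor list and 7.64e-22 for the cell cycle list. With an estimated correlation the adjusted p was 0.0301 for each of the first 3 lists, and the cell cycle call was lost (adjusted p = 0.115 with an estimated correlation). In an exact permutation of the list scores within isolations, the adjusted p was 0.000165 for the oligodendrocyte lineage and cell cycle lists. It was 0.000144 for the astrocyte and the progenitor list, for which the labelled arrangement alone of 55440 gave as large a difference, the smallest p possible. Camera with its fixed correlation also called many lists in other splits of the libraries within isolations. Of 100 splits, the labelled one included, 23 gave 12 or more calls. The median of the others was 8 and the highest 19. The splits leave the difference between the arms in the data, so these counts are not a rate of false calls. The camera adjusted p-values at the fixed correlation, here and below, were thus not shown to control false calls. Taken alone they are not evidence for a single list.

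**Figure D2:**
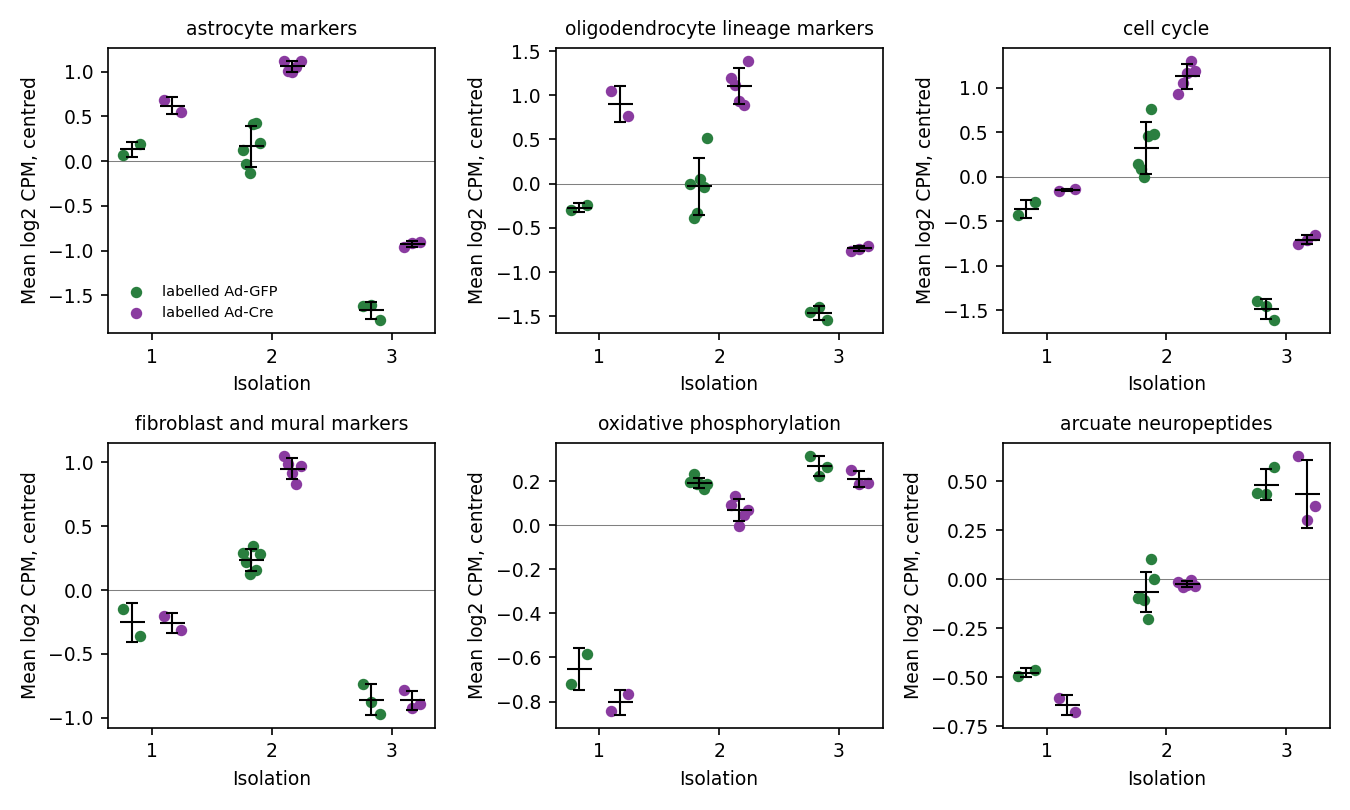
Mean score of 6 gene lists (vertical axes, log2 CPM centred on the mean of each member, scaled separately) in each library, by isolation (horizontal axes); points are libraries, bars are the mean and SD. The astrocyte score of the libraries labelled Ad-Cre lies above that of all libraries labelled Ad-GFP of the same isolation, with a mean difference of 0.49 in isolation 1 and 0.74 in isolation 3, while the arcuate neuropeptide score overlaps in isolations 2 and 3.

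Genes of the Notch, Sonic hedgehog, BMP and Wnt pathways, which act in neural development, also rose over the 3 isolations together. Of 16 tested Notch pathway genes 9 rose and none fell, with Dll3, Notch1 and Hes1 at 0.89 ± 0.10, 0.77 ± 0.09 and 0.81 ± 0.10. Of 12 Sonic hedgehog pathway genes 8 rose and 1 fell, with the co-receptor Gas1 and the signal transducer Smo at 0.94 ± 0.09 and 0.84 ± 0.09 and the transcription factor Gli2 at 1.04 ± 0.13. Of 16 BMP pathway genes 10 rose, with the receptors Bmpr1b and Bmpr1a at 0.91 ± 0.07 and 0.26 ± 0.03 and Id3 at 1.03 ± 0.15. Of 20 Wnt pathway genes 10 rose, with Wnt7b, Fzd2 and Wnt5a at 0.71 ± 0.06, 1.09 ± 0.12 and 0.32 ± 0.04. Adjusted over the list alone, 9 Notch, 8 Sonic hedgehog, 10 BMP and 13 Wnt members rose, and 1 Sonic hedgehog and 1 Wnt member fell. The camera adjusted p was 9.07e-08 for Notch, 3.59e-06 for Sonic hedgehog, 0.000134 for BMP and 7.21e-06 for Wnt genes, and each call was lost when the correlation was estimated (adjusted p = 0.115 with an estimated correlation for each of them). The list score differed by 0.178, 0.565 and 0.212 in isolations 1, 2 and 3 for Notch, by 0.15, 0.623 and 0.137 for Sonic hedgehog, by 0.123, 0.389 and 0.32 for BMP and by 0.166, 0.333 and 0.001 for Wnt genes. Without isolation 2 the median log2 fold change fell from 0.40 to 0.14 for Sonic hedgehog, from 0.18 to 0.09 for BMP and from 0.18 to 0.07 for Wnt genes (camera adjusted p = 0.0203, 0.0143 and 0.0122), and Gli2 and Id3 did not pass. Notch1, Hes1 and Id3 are also in the progenitor list. With the marker score as covariate, the fitted direction of these 4 lists and of the cell cycle, astrocyte and oligodendrocyte lineage lists turned downward without passing, the adjusted p being 0.0503 for the cell cycle list and between 0.15 and 0.838 for the others; the score contains the astrocyte, oligodendrocyte lineage and progenitor genes themselves.

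Markers of fibroblasts and mural cells differed between the arms mainly in isolation 2. Of 16 such markers 10 rose and 2 fell in the main comparison (median 0.39, camera adjusted p = 3.59e-05), with the collagen Col3a1 at 1.76 ± 0.13 and the proteoglycans Dcn and Lum at 1.03 ± 0.13 and 1.25 ± 0.17. Adjusted over the list alone, 10 rose and 3 fell. The median was 0.62 in isolation 2, 0.04 in isolation 1 and -0.09 in isolation 3, and 9 of the 16 genes had a virus by isolation interaction. The call was lost when the correlation was estimated (adjusted p = 0.118 with an estimated correlation), with isolation from the characteristics (adjusted p = 0.136) and with no isolation covariate (0.258), and without isolation 2 the direction turned (adjusted p = 0.694) and Col3a1 and Dcn did not pass. Microglia and endothelial markers gave no list call, with 1 rise and 1 fall among 11 tested and no rise and 1 fall among 8 (camera adjusted p = 0.643 and 0.688). Adjusted over the list alone, neither list had a rise, and each had 1 fall.

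Genes of mitochondrial respiration, cholesterol synthesis and synaptic vesicles were lower in the libraries labelled Ad-Cre, by small amounts. Of 25 oxidative phosphorylation genes 18 fell and none rose (median -0.13), with Cox5a at -0.19 ± 0.03, Cyc1 at -0.17 ± 0.03 and Atp5o at -0.18 ± 0.03. Of 21 cholesterol synthesis genes 12 fell and none rose (median -0.16), with Dhcr7 at -0.30 ± 0.05, Acat2 at -0.26 ± 0.05 and Lss at -0.20 ± 0.04. Of 21 genes of synaptic vesicles and release 9 fell and none rose (median -0.08), with Syp at -0.15 ± 0.03, Snap25 at -0.14 ± 0.03 and Vamp2 at -0.15 ± 0.04. Adjusted over the list alone, 20, 13 and 10 members fell. The camera adjusted p was 1.32e-08, 3.59e-06 and 0.000204 for these lists, and the calls were lost when the correlation was estimated (adjusted p = 0.158, 0.309 and 0.309 with an estimated correlation). Without isolation 2 the synaptic call was lost (adjusted p = 0.428), the oxidative phosphorylation median was -0.0851, and Atp5o, Acat2, Syp, Snap25 and Vamp2 did not pass. In isolations 1, 2 and 3 the median was -0.156, -0.138 and -0.065 for oxidative phosphorylation, -0.198, -0.2 and -0.033 for cholesterol synthesis and -0.082, -0.139 and 0.018 for synaptic genes, and no gene of the 3 lists passed in isolation 3. In the same libraries the astrocyte score was higher by 0.771. With the marker score as covariate the synaptic and cholesterol lists turned upward without passing (adjusted p = 0.514 and 0.138), and the oxidative phosphorylation call was lost (adjusted p = 0.054). Of 20 pan-neuronal genes 7 fell and none rose, with Eno2 at -0.19 ± 0.03, Stmn2 at -0.15 ± 0.03 and Thy1 at -0.17 ± 0.05, and the list did not pass (median -0.07, camera adjusted p = 0.0743). It passed with upper-quartile factors (0.0485), with isolation from the characteristics (0.00749), without isolation 3 (0.00217), with the length trend removed (0.041) and without both doubted libraries (0.0205), while without isolation 2 its direction turned without passing (median 0.0138, adjusted p = 0.745). The pan-neuronal median was -0.055, -0.087 and 0.06 in isolations 1, 2 and 3. When adjusted over the list alone, 8 pan-neuronal genes fell and 1 rose. Stmn2 and Thy1 did not pass without isolation 2.

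The neuropeptide genes of the arcuate nucleus showed 1 change among 10 tested. Pomc, the precursor of the melanocortins, rose by 0.52 ± 0.14 on the log2 scale (edgeR adjusted p = 0.00667), and it did so unequally, with 0.17 ± 0.36 in isolation 1, 0.14 ± 0.16 in isolation 2 and 1.07 ± 0.17 in isolation 3 (adjusted p of the interaction 0.0408). Its call was lost without isolation 3 (0.15, adjusted p = 0.463), with isolation from the characteristics (adjusted p = 0.0891), with counts summed per virus and isolation (0.133) and with isolation as a random effect (0.143). Pomc was at 3.8 ± 3.57 CPM (SD, 10 libraries) and 2.26 ± 1.35 CPM (11 libraries) in the arms. The difference of Agrp was 0.05 ± 0.20, of Npy -0.06 ± 0.07 and of Cartpt -0.02 ± 0.08. Sst was at -0.04 ± 0.05, Pdyn at 0.02 ± 0.05, Gal at -0.13 ± 0.10 and Tac2 at -0.02 ± 0.15. Th was at -0.14 ± 0.08 and Ghrh at -0.38 ± 0.15, with adjusted p of 0.194 and 0.0698. Th was lower in isolation 3, at -0.43 ± 0.11 (edgeR adjusted p = 0.0377), and passed without isolation 2 (0.0397), with an interaction that did not pass (0.115). Ghrh passed without Ad-Cre isolation 2 replicate 4 (0.0343), without Ad-Cre isolation 3 replicate 1 (0.0378) and without both doubted libraries (0.0322). Agrp had a mean of 0.392 CPM over the libraries, so small differences in it were not detectable at this depth. The list gave no call (camera adjusted p = 0.688), and adjusted over the list alone the count was also 1.

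**Figure D3:**
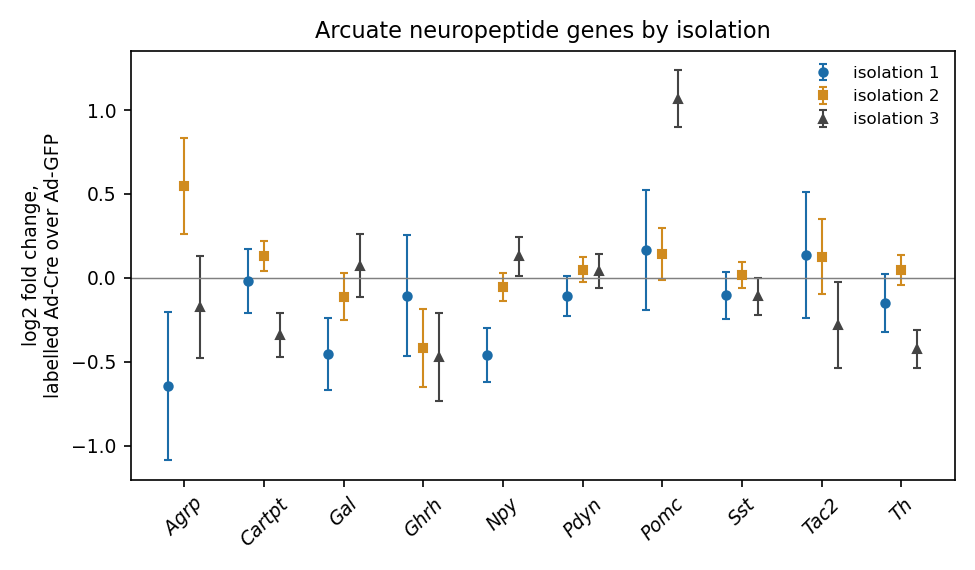
Log2 fold change of the 10 tested arcuate neuropeptide genes (vertical axis, libraries labelled Ad-Cre over Ad-GFP) in each isolation, with SE bars; symbols mark isolations 1, 2 and 3. Pomc lies at 1.07 in isolation 3, at 0.17 in isolation 1 and at 0.14 in isolation 2.

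The other lists were not called by camera. Of 41 hypothalamic transcription factors 9 rose and 4 fell, with Pou3f2 at 0.43 ± 0.07 and Nr5a1, a factor of the ventromedial nucleus, at -0.44 ± 0.08 (camera adjusted p = 0.288). Of 30 energy balance receptor and signalling genes 7 rose and 2 fell, with Ntrk2, the BDNF receptor, at 0.41 ± 0.03, Nr3c1 at 0.34 ± 0.05 and Socs3 at 0.70 ± 0.10 (camera adjusted p = 0.288). Of 17 other hypothalamic neuropeptides Qrfp rose and Trh fell, at 1.51 ± 0.33 and -0.26 ± 0.07 (camera adjusted p = 0.891). Qrfp had a mean of only 0.191 CPM over the libraries. Within isolations it passed in isolation 2 alone (edgeR adjusted p = 0.000447, against 0.572 and 0.703 in isolations 1 and 3). Among 19 genes of peptide processing 3 rose and 5 fell, with Scg5 at -0.18 ± 0.03 (0.53). GABA and glutamate neuron genes gave 2 rises and 2 falls of 10 and 2 falls of 9, with Dlx2 at 0.34 ± 0.08 and Slc17a8 at -0.25 ± 0.06 (adjusted p = 0.688 and 0.344). Among 26 neurotransmitter receptors 2 rose and 5 fell, with Gabra4 at -0.17 ± 0.04 (adjusted p = 0.288). Of 34 interferon response genes 2 rose and 5 fell, with Psmb9 at -0.66 ± 0.14, and of 28 p53 targets 5 rose and 4 fell, with Pmaip1 at -0.30 ± 0.05 (adjusted p = 0.288 and 0.554). Stress response, hypoxia and glycolysis, inflammation, cell cycle inhibitor and early response genes also gave no call (adjusted p = 0.891, 0.648, 0.53, 0.288 and 0.282). Nor did ependymal and pituitary markers (camera adjusted p = 0.286 and 0.53), and the red blood cell list had 2 tested members and was not tested. The fry test, which does not compare a list with other genes, called energy balance genes (adjusted p = 0.00486), cell cycle inhibitors (0.00938) and ependymal markers (0.00464) higher and glutamate neuron genes (0.0477) lower. The permutation of list scores called ependymal markers (adjusted p = 0.0236). Without isolation 2 camera called energy balance (0.00459) and early response genes (0.0203), and with the length trend removed or without isolation 3 it called neurotransmitter receptors lower (0.00874 and 0.0115). Without isolation 2 the neurotransmitter receptors turned and were called higher (0.0146). Without isolation 2, Pou3f2, Trh, Dlx2, Slc17a8, Gabra4 and Psmb9 did not pass. Among the genes of these lists, 5 stress response genes rose and 6 fell, 3 hypoxia and glycolysis genes rose and 2 fell, and 2 inflammation genes rose and 2 fell. Of the cell cycle inhibitors 3 rose and 1 fell, of the early response genes 2 rose and 1 fell, of the ependymal markers 2 rose and 1 fell, and of the pituitary markers 1 fell. Adjusted over the list alone, 12 transcription factors rose and 5 fell, 8 energy balance genes rose and 2 fell, 4 peptide processing genes rose and 6 fell, 6 p53 targets rose and 4 fell, 6 stress response genes rose and 6 fell, 4 hypoxia and glycolysis genes rose and 2 fell, and 1 pituitary marker rose and 1 fell. The counts adjusted over the list alone equalled those over all genes for the other lists of this paragraph. The camera direction was opposite in sign to the median for the stress response list (median -0.002), and to the mean for the other neuropeptides (0.083), hypoxia and glycolysis (0.003) and endothelial (0.002) lists.

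Within the isolations, 307 genes were higher and 226 lower in isolation 1, 2543 and 2325 in isolation 2, and 339 and 89 in isolation 3 (edgeR quasi-likelihood contrasts, 17442 genes tested). With isolation from the characteristics of 1 library the counts were 8, 1757 and 8. Sox10 was called in each of them, at 1.40 ± 0.23, 1.43 ± 0.14 and 2.00 ± 0.36. The fold changes of 12025 genes with a mean of at least 4 CPM correlated across genes with r between 0.476 and 0.542 for the pairs of isolations, where genes are not independent replicates. The isolations share no libraries. For isolations 1 and 3, 83 genes were called higher in both against 6 for independent lists, while 6 were called lower in both against 1.2. Isolations 2 and 3 shared 224 higher calls against 49.4 for independent lists. Leaving out Ad-Cre isolation 1 replicate 1, Ad-Cre isolation 1 replicate 2 or Ad-GFP isolation 1 replicate 2 lowered the isolation 1 count from 533 to 52, 254 or 81. The isolation 3 count fell from 428 to 199 or 198 without Ad-Cre isolation 3 replicate 2 or 3, and to 248 or 127 without Ad-GFP isolation 3 replicate 1 or 3.

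The response differed between isolations for 777 genes (edgeR interaction test, 2 degrees of freedom), of which 402 were also among the 4541. The 5 with the smallest adjusted p were led by the collagen Col1a2, at 0.10 ± 0.15, 1.47 ± 0.07 and -0.29 ± 0.14 in isolations 1, 2 and 3 (adjusted p = 6.69e-08), and Cyp1a1, a target of the aryl hydrocarbon receptor, at 0.52 ± 0.24, 1.10 ± 0.10 and -0.34 ± 0.12 (adjusted p = 2.91e-05). Spock3 was at -0.04 ± 0.06, -0.43 ± 0.04 and 0.06 ± 0.05, the transcription factor Sp1 at 0.26 ± 0.07, 0.42 ± 0.04 and -0.18 ± 0.06, and Ctnna1, a linker of cadherins, at 0.64 ± 0.07, 0.68 ± 0.04 and 0.14 ± 0.06. Tbx3 itself gave an adjusted p of 0.116. With isolation from the characteristics 8 genes passed, and 484 after thinning to the smallest library. The number of genes also depended on single libraries, from 327 without Ad-Cre isolation 1 replicate 2 to 1461 without Ad-GFP isolation 2 replicate 4.

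The isolations differed from each other far more than the arms did. Among the 11 Ad-GFP libraries, 13939 of 17145 tested genes (81.3%) differed between isolations, 4373 of them by at least 2-fold between some pair (edgeR, 2 degrees of freedom). The CPM levels in this comparison were scaled among these 11 libraries alone, while the list scores were scaled and centred over all 21 libraries. Early response genes were highest in isolation 1: Fos was at 882 ± 102 CPM (n = 2) there, at 78.2 ± 9.22 CPM (n = 6) in isolation 2 and at 40.1 ± 0.865 CPM (n = 3) in isolation 3, and Npas4 was at 438 ± 36.3, 27.1 ± 4.59 and 20.5 ± 2.58 CPM. The mean astrocyte, oligodendrocyte lineage and cell cycle scores were lowest in isolation 3, at -1.668, -1.464 and -1.485. Mki67 was at 3.04 ± 0.29 CPM there, against 25.7 ± 3.85 and 35.9 ± 6.11 CPM in isolations 1 and 2. The microglia score was not lowest there, at 0.233 against 0.174 and -0.127 in isolations 1 and 2. Pomc was at 0.776 ± 0.166, 1.8 ± 0.197 and 4.19 ± 0.801 CPM, and Npy at 7.29 ± 0.608, 14.6 ± 2.1 and 13.3 ± 0.993 CPM. All 10 arcuate neuropeptide genes and 24 of 25 oxidative phosphorylation genes passed the threshold.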

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

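The tests of cell composition, of exchanged labels and of exons and the splits that kept the effect shared by the isolations were chosen only after the results were seen, and the wording of the fibroblast test was set after its value was known. The depth, length and other split tests were written before their results.

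Tbx3 was higher in the libraries labelled Ad-Cre (log2 fold change 1.01). In isolation 3 it rose by 0.48 ± 0.127 (SE) more than the mean score of the astrocyte, oligodendrocyte lineage and progenitor lists. This argues there only against an equal rise of all these cells as the source, since a mean over 3 lists cannot judge a single kind of cell. The fibroblast and mural score differed in isolation 3 by -0.006 ± 0.081 against 1.14 for Tbx3. This argues there against fibroblasts and mural cells, taken as a whole, as the source. In isolation 2 the difference of Tbx3 from the glial and progenitor score was -0.359 ± 0.244. The fibroblast and mural score was higher there by 0.714 ± 0.051 against 0.54 for Tbx3, so both sets of cells stay open in isolation 2. In isolation 1, where Tbx3 was higher by 1.31, neither set was tested. Astrocytes or another subset of glial cells stay open in isolation 3. Sox10 was higher there by 2.00 and the astrocyte marker Aldoc by 1.18 ± 0.19, with a median of 0.753 for the astrocyte list. With the glial and progenitor score as a covariate Tbx3 was at 2.00 ± 0.34 (adjusted p = 0.0536), which decides nothing since the score follows the virus labels (r = 0.95). Reads over exons outside the loxP sites can keep the count of the whole gene from falling. The rise of 1.01 ± 0.11 cannot test their part, since it is the observation to be explained. Any rise in transcripts of the deleted allele would be counted through the same exons. An exchange of the virus labels, which could give the rise in 3 of 3 isolations, stays open. So does a biological rise in Tbx3 expression after deletion, which was not tested.

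Glial, progenitor and cycling genes were higher in the libraries labelled Ad-Cre. A lower share of neurons would raise markers of every other cell type alike. In isolation 3 the astrocyte score rose by 0.745 ± 0.075 more than the fibroblast and mural score. The endothelial score differed by -0.08 there and the pan-neuronal score by 0.052, which argues against a lower share of neurons as the whole cause in isolation 3. Members with a mean below 1 CPM were not left out of these scores. In isolation 2 the astrocyte score rose by 0.855 ± 0.142 more than the endothelial score. The excess was 1.09 ± 0.126 over the 4 endothelial markers with a mean of at least 1 CPM. However, the fibroblast and mural score was higher by 0.714 in isolation 2, against 0.892 for astrocytes, so the comparisons disagree and decide nothing there. The fibroblast and mural list also holds Thy1, a pan-neuronal gene, and Cspg4, of the oligodendrocyte lineage list. Thinning to the smallest library left the median of the 77 genes at 0.761 against 0.767. Thinning keeps the expected share of each gene in its library, so this value could hardly move and decides nothing on sequencing depth. What stays open besides depth is a lower share of neurons in isolations 1 and 2 and a change in the glial or dividing cells themselves. In isolation 1 the share of neurons was not tested. Whether either may follow the deletion, Cre itself or the dose of either virus stays open too. No culture with Cre and without loxP sites was analysed here.

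Oxidative phosphorylation, synaptic vesicle, cholesterol synthesis and Hist1 histone genes were lower in the libraries labelled Ad-Cre. Log2 fold changes rose with transcript length across genes (Spearman's rho 0.289 over 11588 genes, which are not independent), so short transcripts could be lower for technical reasons. With that trend removed in each library, the medians were -0.0958, -0.0843, -0.168 and -0.728 against -0.133, -0.0804, -0.161 and -0.775, which argues against length as the whole cause in each of these sets. Reads shared between histone genes, and for the synaptic genes a share of neurons lowered by more glial cells, were not tested and stay open.

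Other splits of the same libraries, with the virus labels permuted within isolations, were compared with the real one. Of 100 splits only the real one gave as many genes as the 4541 (1 of 100, highest other 233). For the 777 interaction genes these splits (1 of 100, highest other 416) assume no effect of the virus at all. They were repeated with the effect shared by the isolations kept out of the permutation (1 of 100, highest other 95). The 4868 genes of isolation 2 were also reached by the real split alone (1 of 100, highest other 2125). A random division of separate libraries is thus an unlikely source of these 3 counts. However, the splits treat each library as a separate culture, which the labels do not say. If libraries of one arm and isolation shared a culture, a difference between cultures could not be excluded. In isolation 3 there are 10 splits, too few for a share under 0.05, and the real one gave 428 genes against a highest other of 1. For the number of gene lists called by camera, 23 of 100 splits gave 12 or more (highest other 19, median of the others 8). Chance thus cannot be excluded for that count, though these splits also assume no effect of the virus and were not repeated with it removed. For the same reason the camera adjusted p of a single list, at the fixed correlation, is not evidence for that list by itself. The permutation of list scores called the same 12 lists and ependymal markers, but it tests each list against no difference and does not compare it with other genes.

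Samples that stood apart from their group were looked for in the 2 groups of isolation 2, where chance marks about 1 in 20 of the 130 comparisons (6.5) and 11 were marked. Ad-GFP isolation 2 replicate 4 had a total of 19778437 counts (19.78 when scaled like the 25.9 to 29.4 of the other 5). It also had the highest Gfap at 36.9 CPM, Osmr at 2.08 CPM and Plscr4 at 1.42 CPM. Tbx3 was at 1.89 CPM in Ad-Cre isolation 2 replicate 2, against 1.33 to 1.47 CPM in the other 4, and the pan-neuronal score there was -0.00778. The early response score of Ad-GFP isolation 2 replicate 6 was -0.947, Hist1h2bg was at 2.24 CPM in Ad-GFP isolation 2 replicate 3, and Agrp was at 0.489 CPM in Ad-Cre isolation 2 replicate 3. Ad-GFP isolation 2 replicate 5 had Cartpt at 15.9 CPM and Sst at 244.5 CPM.

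The difference between virus arms itself differed between isolations for 777 genes by the interaction test. Among named genes the adjusted p was 6.69e-08 for Col1a2, 2.91e-05 for Cyp1a1, 0.000244 for Spock3 and for Sp1, and 0.000724 for Ctnna1. It was 0.0408 for Pomc, 0.00407 for Id3, 0.00391 for Notch1, 0.0283 for Hes1 and 0.0287 for Pdgfra. It was 0.00677 for Col3a1, 0.0458 for Dcn, 0.0394 for Fzd2 and 0.0352 for Bmpr1a. It was 0.0198 for Nr3c1 and 0.0423 for Slc7a11. For genes that were lower it was 0.0379 for Syp, 0.0224 for Snap25, 0.0498 for Acat2 and 0.0195 for Stmn2.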

How the results depend on the processing

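The alternatives chosen after seeing the data were the length correction, the non-neuronal covariate, the fit without both doubted libraries, upper-quartile scaling of the lists and the permutation of list scores. The count of 4541 genes stayed within 1.5 times under both other scalings, DESeq2, limma-voom, both other filters, thinning, the random effect, the length correction, the fit without both doubted libraries and the fits without isolation 1 or 3. It was 49 with no isolation covariate, 1646 with isolation from the characteristics, 730 with counts summed per virus and isolation (fewer samples), 590 with a 1.5-fold limit and 0 with the non-neuronal score as covariate, which follows the virus labels (r = 0.95). Without 1 isolation it ran from 1239 to 4384 and without 1 library from 3844 to 4669. With upper-quartile factors 46.6% of the genes were higher and with no filter 62.9%, against 54.5%. The log2 fold change of Tbx3 ran from 0.93 to 1.05 without 1 library and from 0.89 to 1.20 without 1 isolation, and it was 1.52 (adjusted p = 0.0268) with isolation from the characteristics and 0.77 (0.0456) with isolation as a random effect. It no longer passed with no isolation covariate (1.21) or with the non-neuronal score (2.00), where the direction held. The replicate number as a block gave 3715 genes and a log2 fold change of 1.01 for Tbx3, and it changed no list call. Of the 10 same-numbered pairs 5 correlated above 0.1 (from -0.386 to 0.443), so the numbers were not taken to pair the libraries, and 6 of 20 libraries correlated best with their own number.

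Within isolations, isolation from the characteristics gave 8, 1757 and 8 genes. Without 1 library the counts ran from 52 to 765 in isolation 1, from 3980 to 5412 in isolation 2 and from 127 to 542 in isolation 3. The interaction gave 8 genes with isolation from the characteristics and 484 after thinning, and without 1 library from 327 to 1461. It moved by over 1.5 times without Ad-Cre isolation 1 replicate 1 (422) or 2 (327), Ad-GFP isolation 1 replicate 2 (395), Ad-Cre isolation 2 replicate 4 (374) or 5 (506), Ad-GFP isolation 2 replicate 2 (473), 4 (1461), 5 (1299) or 6 (498), Ad-Cre isolation 3 replicate 2 (402) or 3 (371), and Ad-GFP isolation 3 replicate 1 (507), 2 (504) or 3 (372). Genes differing between isolations in Ad-GFP ran from 13098 to 14331 without 1 library. Of the 12 lists, 3 were called with an estimated correlation and all 12 by fry, which called 16. The fibroblast and mural list lost its call with isolation from the characteristics (adjusted p = 0.136) and with no isolation covariate (0.258). Without isolation 1, 2 or 3 the adjusted p of the neurotransmitter receptor list was 0.141, 0.0146 (a rise) and 0.0115, and without isolation 2 or 3 that of the fibroblast and mural list was 0.694 (a fall) and 9.75e-06. Without isolation 2 the log2 fold changes of Col1a2, Cyp1a1 and Spock3 changed sign, to -0.1137, -0.2065 and 0.0167, and without isolation 3 Col1a2 was at 1.25 and Spock3 at -0.32.

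The non-neuronal score as covariate called 6 lists, none of them among the 12, and it is partly made of the genes it was applied to. The fitted direction turned for 12 lists, with adjusted p of 0.514 for synaptic vesicles, 0.0085 for neurotransmitter receptors and for the stress response, 0.0503 for the cell cycle, 1.86e-05 for p53 targets, 0.138 for cholesterol synthesis, 0.586 for Sonic hedgehog, 0.838 for Wnt, 0.548 for BMP and for the oligodendrocyte lineage, 0.15 for Notch and 0.705 for astrocytes. It turned for 30 of 125 named genes, none of which then passed. Their log2 fold changes were Mag -0.75, Osmr -1.35, Col1a2 -0.26, Cyp1a1 -0.47, Sp1 -0.29, Qrfp -0.57, Dlx2 -0.17, Dlx5 -0.0859, Junb -0.22, Nes -0.0364, Fas -0.17, Ckap2 -0.44, Cdkn2c -0.0536, Vcam1 -0.58, Pdia4 -0.14, Smo -0.11, Gli2 -0.29, Id3 -0.56, Notch1 -0.0221, Hes1 -0.32 and P2ry12 -1.09 among genes that had risen, and Il28ra 0.0562, Spock3 0.14, Stmn2 0.0314, Syp 0.01, Snap25 0.0864, Vamp2 0.0311, Dusp1 0.26, Dhcr7 0.10 and Egfl7 0.21 among genes that had fallen. The cause of these changes was not tested where none is given. Of 107 named genes that passed, 101 kept their direction but no longer passed with no isolation covariate, 77 with the non-neuronal score, 41 with counts summed per virus and isolation, 38 without isolation 2, 35 with isolation from the characteristics, 10 with isolation as a random effect, 7 with the replicate block, 7 without isolation 1, 6 without both doubted libraries and at most 4 without any 1 library. A direction that was not called in either fit was not counted as changed. Thinning lowered the main count to 3924: the 849 genes lost had a median of 12.6 CPM and 15.3% of them were below 1 CPM, against 27.5 CPM and 4.8% of the 3692 kept.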

Other observations

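The tested features with Hist cluster names were lower or did not pass, which was noticed after the values were seen. Histone genes under other symbols were not examined as a set. Of 22 Hist1 cluster genes 18 were lower and none higher in the libraries labelled Ad-Cre (median log2 fold change -0.78), with medians of -0.55, -0.67 and -1.02 in isolations 1, 2 and 3. Over 32 named histone features 24 were lower and none higher, and the median held its sign under each scaling (-0.772 with RLE and -0.789 with upper-quartile factors for the Hist1 genes). Cell cycle genes were higher in the same libraries. Of 10 tested cell cycle inhibitors 3 rose and 1 fell, and the list was not called (camera adjusted p = 0.288). Among them Cdkn2c was higher by 1.01 ± 0.11 (SE) on the log2 scale. The histone family members may share reads, and with the length trend removed the Hist1 median was -0.728.

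Between isolations 3 and 2 of the Ad-GFP libraries Tbx3 differed by 2.84 on the log2 scale, against 1.01 between the arms. The arcuate neuropeptide score of the Ad-GFP libraries was highest in isolation 3, at 0.482 ± 0.078, against -0.479 ± 0.023 in isolation 1 and -0.066 ± 0.104 in isolation 2.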
